A study of Apera spica-venti with 32 samples.

How the data were processed

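RNA was measured in leaves of Apera spica-venti (silky windgrass), a grass weed, from 4 populations: S1 and S2, susceptible to herbicides, and R1 and R2, resistant to multiple herbicides. Plants were left untreated or were sprayed with pinoxaden, a herbicide that inhibits acetyl-CoA carboxylase, at 45 g of active ingredient per ha, and sprayed leaves were taken 8 h later. Each of the 8 combinations of population and treatment had 4 biological replicates of 3 plants, which gave 32 libraries of ribosome-depleted, strand-specific total RNA. Per the labels, the authors used FastQC 0.11.5, STAR 2.5.2b, DESeq2 1.24.0 and R 3.6.1; the settings of the assembly, the alignment and the counting are not stated.

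The deposited count table holds raw counts of 39590 open reading frames (here features) on 29344 assembled transcript contigs, in 32 columns, all of which matched a labelled library. The values are whole numbers and carry no normalization. A second deposited table holds the authors' log2 fold changes and, beside them, the adjusted p-value that the authors computed for 4 comparisons, listed only for features below 0.05, together with a description of each feature. Descriptions exist for 7967 features and only for features that the authors listed as differentially expressed; 7697 of them were tested here and 270 were not. No genome was used here, so features have no chromosomal position and are named by description and contig identifier as deposited. Several features can lie on 1 contig, and a description can be shared by several features, so features are not independent genes.

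Features were filtered with filterByExpr of edgeR 4.0.16 (R 4.3.3) by the 8 groups, which left 25036 features on 20677 contigs; 3818 features had no count in any library. Libraries were scaled with TMM factors. A quasi-likelihood negative binomial model with 8 group means and robust dispersions was fitted to all 32 libraries, with 24 residual degrees of freedom and a common biological coefficient of variation of 0.389. Contrasts between group means, each population weighted equally, were tested with the quasi-likelihood F test, and p-values were adjusted by the Benjamini-Hochberg method over the 25036 features of 1 contrast. A feature is said to be called, or to have risen or fallen, when its adjusted p is under 0.05; no fold threshold was used. Fold changes are log2 values ± the standard error (SE) of the fit. Group levels are CPM (counts scaled to a common library size) with the TMM factors, given as mean ± SD over the 4 libraries of a group. The p-values describe these 4 populations, since each class holds only 2.

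The comparisons, tests, named-feature rule, gene lists and alternative settings were fixed before the data were examined. The named features were chosen by rule for each of the class comparisons in untreated and in sprayed plants, the responses of susceptible and of resistant plants, and the difference between these responses. The rule takes the 5 called features with the smallest p in each direction with an absolute log2 fold change of at least 1 and the same sign in each population contrast, 1 per description and none described only as uncharacterized, hypothetical, unknown, predicted or unnamed (for the difference between responses, 3 in each direction). It adds the member with the smallest p in each direction of each of 8 priority gene lists, and every tested acetyl-CoA carboxylase. Gene lists were word patterns searched in the descriptions: 31 lists, of which 8 were priority lists for detoxification and defence, 15 were secondary lists and 8 were controls for tissue composition and foreign RNA. For each list the members called in each direction were counted, once with p adjusted over all features and once adjusted over the list alone. Because only features that the authors had listed on these same libraries carry a description, no list could be compared with a full background, and list counts are not independent evidence of a direction.

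Responses of the classes were compared by the count of features called in the same direction with Fisher's exact test, and by the correlation of log2 fold changes across features. Composition measures of each library (total, scaling factor, share of features detected, share of counts in the 10 most abundant features, shares in the control lists) were compared by two-sided permutation tests, exact for groups of 4. Principal components were computed on log2 CPM with a prior count of 2. Replicate numbers were checked as a possible pairing, and libraries were checked for duplicates. A feature with no count in a group was given a floor of 3 counts over the group, and ratios from few counts carry 95% intervals for counting error only. The test was also tested on simulated data with real means, depths and dispersions. For the 5 contrasts above, changes of 2-fold were called in 47%, 53%, 44%, 54% and 37% of features and changes of 4-fold in 80%, 76%, 85%, 77% and 61%. Of the simulated calls, 5.9%, 3%, 4.4%, 4.4% and 7.5% were false. Simulated features were drawn independently, with no difference between populations of a class and no library that stood apart. The false shares therefore do not cover such conditions.

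Library totals ranged from 26213780 to 46062806 counts, with a median of 34342951; between 9088248 and 14691660 counts per library fell outside the 10 most abundant features.

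The alternative settings chosen then were median-of-ratios size factors, library totals without composition factors, no low-count filter, a filter of at least 1 CPM in at least 4 libraries, DESeq2 1.42.0, limma-voom (limma 3.58.1), a stricter p of 0.01, an added absolute log2 fold change of at least 1, the replicate number as a block, 4 pooled groups, population as a random block, only the libraries compared, and leaving out each library or population. After the data had been seen, sums per contig, removal of the 10 most abundant features, a covariate for histone and cell-division transcripts, and a competitive list test (camera) with a rotation test (fry) within the described features were added. No library was left out of the main comparisons.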

Results

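Transcript counts were measured in leaves of 4 populations of the grass weed Apera spica-venti, with and without the herbicide pinoxaden. S1 and S2 are susceptible and R1 and R2 are resistant to multiple herbicides; each population gave 4 untreated libraries and 4 libraries from plants sprayed 8 h earlier. Mean totals of untreated libraries were 40467000 ± 5871000 counts in S1, 36788000 ± 4934000 in S2, 29508000 ± 3357000 in R1 and 36639000 ± 6634000 in R2 (SD, n = 4). Mean totals of sprayed libraries were 33697000 ± 4447000 in S1, 31181000 ± 575500 in S2, 30738000 ± 1995000 in R1 and 36709000 ± 1585000 in R2 (SD, n = 4).

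Plastid messages dominated the counts. The ribulose-1,5-bisphosphate carboxylase/oxygenase large subunit, which fixes carbon dioxide, held 24.4% of all counts on average, and 2 reading frames of the photosystem II protein D1 held 13.46% and 9.377%. The 10 most abundant features together held a mean of 64.776% of counts in untreated resistant libraries and 67.623% in untreated susceptible libraries, and the TMM factors averaged 1.0199 and 0.87724 in the same groups. Neither difference passed the correction over 78 composition tests (adjusted p = 0.05152 for both; raw p = 0.002486 and 0.000777, two-sided permutation tests). With library totals alone, the median log2 fold change over all features moved to 0.21 for the untreated class difference, to 0.30 for the susceptible response, to 0.43 and 0.18 for S1 and S2, to -0.31 for the difference between the responses and to -0.15 between untreated R2 and R1. Directions below are relative to the TMM scale, on which these medians lie between -0.02 and 0.01.

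**Figure D1:**
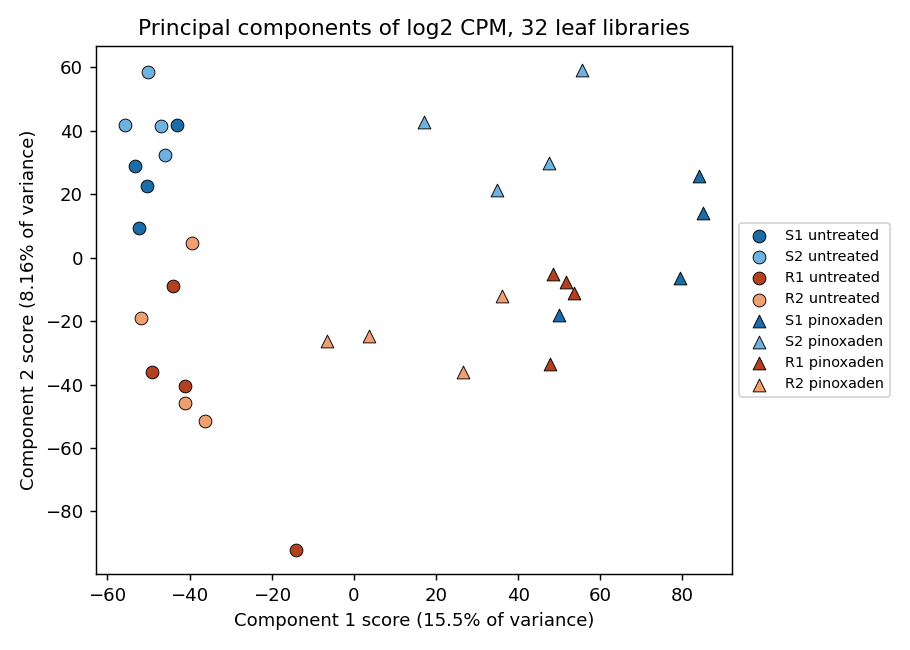
Scores of the 32 libraries on the first principal components of log2 CPM, with 15.5% of the variance on the x axis and 8.16% on the y axis; circles are untreated and triangles sprayed libraries, and colours mark the populations. Sprayed libraries lie to the right of untreated libraries of their population, and untreated R1 replicate 1 has the lowest score on the y axis, -92.25.

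Untreated R1 replicate 1 had extreme values within its group, though no composition measure of it passed the outlier test. Its TMM factor was 1.236 (others 0.985 to 1.07), its 10 most abundant features held 60.5% of counts (others 63.9 to 66.1), and its share of histone and cell-division transcripts was 0.086%, against a mean of 0.0584% in untreated resistant and 0.0444% in untreated susceptible libraries. These values stand beside the untreated class difference below, where the count without this library is given.

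The comparison of untreated resistant with untreated susceptible plants asks which transcripts differed before any spraying. Enzymes and carriers of detoxification were among the higher transcripts. UGT75K6 (TRINITY_DN256_c0_g1_i3.p1), a glycosyltransferase of the family that attaches sugars to small molecules, rose by 4.67 ± 0.39 on the log2 scale, from 0.553 ± 0.128 CPM in S1 and 0.624 ± 0.361 in S2 to 12.6 ± 1.28 in R1 and 18.6 ± 7.69 in R2 (SD, n = 4; adjusted p = 1.12e-07). UDP-glycosyltransferase UGT75E2 (TRINITY_DN9231_c0_g1_i1.p1) was 2.61 ± 0.27 higher and a glutathione transferase (TRINITY_DN854_c0_g1_i8.p1), of the enzymes that conjugate glutathione to foreign compounds, 2.09 ± 0.27 higher. Protein DETOXIFICATION 27 (TRINITY_DN5437_c0_g1_i12.p1), named for a family of efflux carriers, was 1.66 ± 0.20 higher, and ABC transporter C family member 10-like (TRINITY_DN512_c0_g1_i24.p1) was 2.15-fold higher. Cytochrome P450 709B1-like (TRINITY_DN16815_c1_g1_i18.p1), a member of the haem monooxygenases, was 2.61 ± 0.45 higher at low levels, from 0.144 ± 0.0741 CPM in S1 and 0.0876 ± 0.0711 in S2 to 0.731 ± 0.7 in R1 and 0.712 ± 0.511 in R2 (SD, n = 4). Its R1 values were 1.77, 0.462, 0.477 and 0.219 CPM, and without untreated R1 replicate 1, the highest, the log2 fold change of TRINITY_DN16815_c1_g1_i18.p1 was 2.14 and still called; the call was lost in 4 of 50 settings. An alanine--glyoxylate aminotransferase 2 homolog 3 (TRINITY_DN57_c0_g2_i2.p3) was 2.71 ± 0.31 higher. Adjusted p for the features named after UGT75K6 ran from 9.93e-07 for UGT75E2 to 0.00169 for the P450.

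Among the priority lists, 9 of 44 cytochrome P450 members, 8 of 16 glutathione S-transferases and 12 of 45 glycosyltransferases were higher in untreated resistant plants and none was lower; adjusted over the list alone, 14, 10 and 22 were higher and 1, 0 and 1 lower. These lists hold only features that the study had chosen as differentially expressed on these samples, here and in every count below, so the counts adjusted over the list alone are not independent evidence. The P450 list caught 9 cyclophilins and P450 reductases by their names; without them the count was again 9 of 35 higher. ABC transporters were called in both directions, with 4 of 43 higher and 2 lower (adjusted over the list alone, 6 and 4). The lower members included ABC transporter G family member 38-like (TRINITY_DN21407_c1_g2_i4.p2), which was 2.14-fold lower (adjusted p = 0.0334), a call lost in 18 of 49 settings, 8 of them without a single library.

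Calls in the NLR, receptor-like kinase and pathogenesis-related lists went in both directions. Of 36 disease resistance proteins of the NLR type, the intracellular immune receptors, 1 was higher and 6 were lower (adjusted over the list alone, 4 and 10), a direction that turned to 5 higher and 2 lower with library totals alone. Disease resistance protein RPP13-like (TRINITY_DN35003_c0_g1_i1.p1) was 3.11 ± 0.51 higher, and putative disease resistance protein RGA4 (TRINITY_DN10924_c1_g1_i4.p1) fell by 0.98 ± 0.16. Of 86 receptor-like kinases, 3 were higher and 6 lower (10 and 14 adjusted over the list alone; 12 higher and 5 lower with library totals alone), with probable LRR receptor-like serine/threonine-protein kinase At2g16250 (TRINITY_DN17136_c0_g1_i10.p1) at 0.65 ± 0.15 and probable receptor-like protein kinase At2g42960 isoform X1 (TRINITY_DN6288_c0_g1_i1.p2) at -0.54 ± 0.12. Of 31 pathogenesis-related features, 4 were higher and 1 lower (7 and 4 adjusted over the list alone), among them glucan endo-1,3-beta-glucosidase-like (TRINITY_DN3963_c0_g2_i2.p4), of the enzymes that cleave beta-1,3-glucans, at 0.73 ± 0.12, and Glucan endo-1,3-beta-glucosidase 14 (TRINITY_DN10141_c0_g1_i14.p1) at -0.38 ± 0.11 (adjusted p = 0.0497). The last call, the only lower one of its list, was lost in 36 of 50 settings, 23 of them without a single library, and the call of At2g16250 was lost without untreated R1 replicate 1. None of the 19 WRKY transcription factors was called with edgeR, also when adjusted over the list alone; 2 were higher with library totals alone.

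Further named features were lower in untreated resistant plants. Reticulon-like protein B8 (TRINITY_DN2015_c0_g1_i6.p1), of a family that shapes the endoplasmic reticulum, fell by 1.09 ± 0.17 and SRG1-like protein (TRINITY_DN4070_c0_g1_i19.p1) by 1.14 ± 0.21. Speckle-type POZ protein (TRINITY_DN58876_c0_g1_i7.p1) was 2.3-fold lower. A lipoxygenase (TRINITY_DN561_c0_g1_i1.p1), of the enzymes that oxygenate polyunsaturated fatty acids, fell by 1.35 ± 0.28. A putative polyprotein (TRINITY_DN29509_c0_g2_i1.p1) had 1 count in untreated resistant and 72 counts in untreated susceptible libraries, a ratio of 0.014 with a 95% counting interval of 0.000349 to 0.0804. Of the features described as acetyl-CoA carboxylase, the enzyme that pinoxaden inhibits, none was called, and the descriptions do not show which of them, if any, encodes the form that the herbicide acts on: acetyl-coenzyme A carboxylase (TRINITY_DN1720_c0_g2_i1.p1) differed by 0.24 ± 0.09 (adjusted p = 0.123) and cytosolic acetyl-CoA carboxylase 2 (TRINITY_DN1720_c0_g1_i7.p1) by 0.04 ± 0.09 (adjusted p = 0.855).

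In all, 1032 of 25036 features were called between the untreated classes, 691 higher and 341 lower in resistant plants (3124 and 141 with library totals alone). Without untreated R1 replicate 1 the count was 298, and without that library 3 P450 members, 6 glutathione S-transferases and 6 glycosyltransferases were higher. The count moved by over 1.5 times without each of 7 other libraries (465, 605 and 609 without S1 replicates 1, 2 and 4; 459 and 631 without S2 replicates 3 and 4; 473 and 386 without R2 replicates 2 and 3, all untreated), and with population as a random block it was 166. It was 200 without R1, 187 without S1 and 144 without S2.

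The comparison of the classes after spraying asks which of these differences stood in the presence of the herbicide. UGT75K6 was again higher in resistant plants, by 3.14 ± 0.34, at 31.3 ± 9.95 CPM in R1 and 48.8 ± 41.4 in R2 against 8.75 ± 2.85 in S1 and 2.21 ± 1.39 in S2 (SD, n = 4; adjusted p = 1.23e-05). UGT75E2 (1.05 ± 0.23), the aminotransferase (1.23 ± 0.28), glutathione transferase TRINITY_DN854_c0_g1_i8.p1 (1.00 ± 0.26) and DETOXIFICATION 27 (0.83 ± 0.20) stayed higher. P450 709B1-like (0.73 ± 0.31) and ABC transporter C family member 10-like (0.51 ± 0.17) were no longer called (adjusted p = 0.23 and 0.113, quasi-likelihood F test). A cytochrome P450 (TRINITY_DN884_c0_g1_i6.p1) was 1.21 ± 0.17 higher, a GST (TRINITY_DN2513_c0_g1_i7.p2) 1.17 ± 0.18 higher and RPP13-like TRINITY_DN35003_c0_g1_i1.p1 3.17 ± 0.53 higher. Probable F-box protein At5g04010 (TRINITY_DN139345_c0_g1_i1.p1), named for the substrate-binding part of ubiquitin ligases, was 3.71 ± 0.58 higher, at low counts given below. RGA4 TRINITY_DN10924_c1_g1_i4.p1 fell by 1.32 ± 0.15 and RGA4 TRINITY_DN10759_c0_g1_i42.p1 by 1.76 ± 0.33. Putative cysteine-rich receptor-like protein kinase 20 (TRINITY_DN21001_c0_g1_i4.p1) fell by 1.65 ± 0.30 and a putative LRR receptor-like serine/threonine-protein kinase (TRINITY_DN3284_c2_g1_i23.p1) by 1.25 ± 0.23. The putative polyprotein had 1 count in sprayed resistant and 57 in sprayed susceptible libraries (ratio 0.0178, 95% counting interval 0.000442 to 0.103). Reticulon-like protein B8 and Speckle-type POZ protein also stayed lower. SRG1-like protein, the lipoxygenase and ABC transporter G family member 38-like were no longer called.

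Detoxification lists again held more higher than lower members: 5 of 44 P450, 5 of 16 glutathione S-transferase and 5 of 45 glycosyltransferase members were higher and 0, 0 and 2 were lower (adjusted over the list alone, 7, 7 and 10 higher and 0, 2 and 9 lower). UGT85F25 (TRINITY_DN256_c1_g1_i2.p1) was among the lower ones at -0.90 ± 0.23. Of the ABC transporters 2 were lower and 0 higher (12 and 2 adjusted over the list alone), with ABC transporter B family member 20-like (TRINITY_DN28236_c1_g2_i1.p1) at -0.95 ± 0.22. Of the WRKY factors, which regulate defence genes, 3 of 19 were lower and 0 higher (8 and 0 adjusted over the list alone), with WRKY4 transcription factor (TRINITY_DN1140_c0_g1_i8.p1) at -0.65 ± 0.15. Of the receptor-like kinases 6 were lower and 1 higher (11 and 2 adjusted over the list alone), with cysteine-rich receptor-like protein kinase 6 (TRINITY_DN1008_c0_g2_i1.p1) at -0.68 ± 0.12 and kinase 10 (TRINITY_DN5640_c1_g1_i4.p1) at 1.42 ± 0.37. The calls of UGT85F25 and kinase 10 were lost in 17 and 19 of 49 settings, 9 and 11 of them without a single library. NLR proteins were called 1 higher and 3 lower (2 and 7 adjusted over the list alone), and no pathogenesis-related member was called with edgeR over all features (1 higher and 3 lower adjusted over the list alone).

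In all, 576 features were called between the sprayed classes, 388 higher and 188 lower in resistant plants (126 and 185 with library totals alone). Of the 1032 features called in untreated plants, 98 were called in the same direction after spraying. The count was 304 without sprayed R2 replicate 3, 371 without sprayed R2 replicate 2, 349 without sprayed S2 replicate 2, and 316 with the populations pooled into 4 groups. It was 120 without R2, 98 without S1 and 1204 without S2. By pair of populations the calls were uneven, with 813 higher and 644 lower in sprayed R2 against S1, 191 and 56 in R1 against S1, 69 and 33 in R1 against S2, and 34 and 14 in R2 against S2. Neither acetyl-CoA carboxylase was called (0.19 ± 0.09 with adjusted p = 0.313 and 0.09 ± 0.09 with adjusted p = 0.709).

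**Figure D2:**
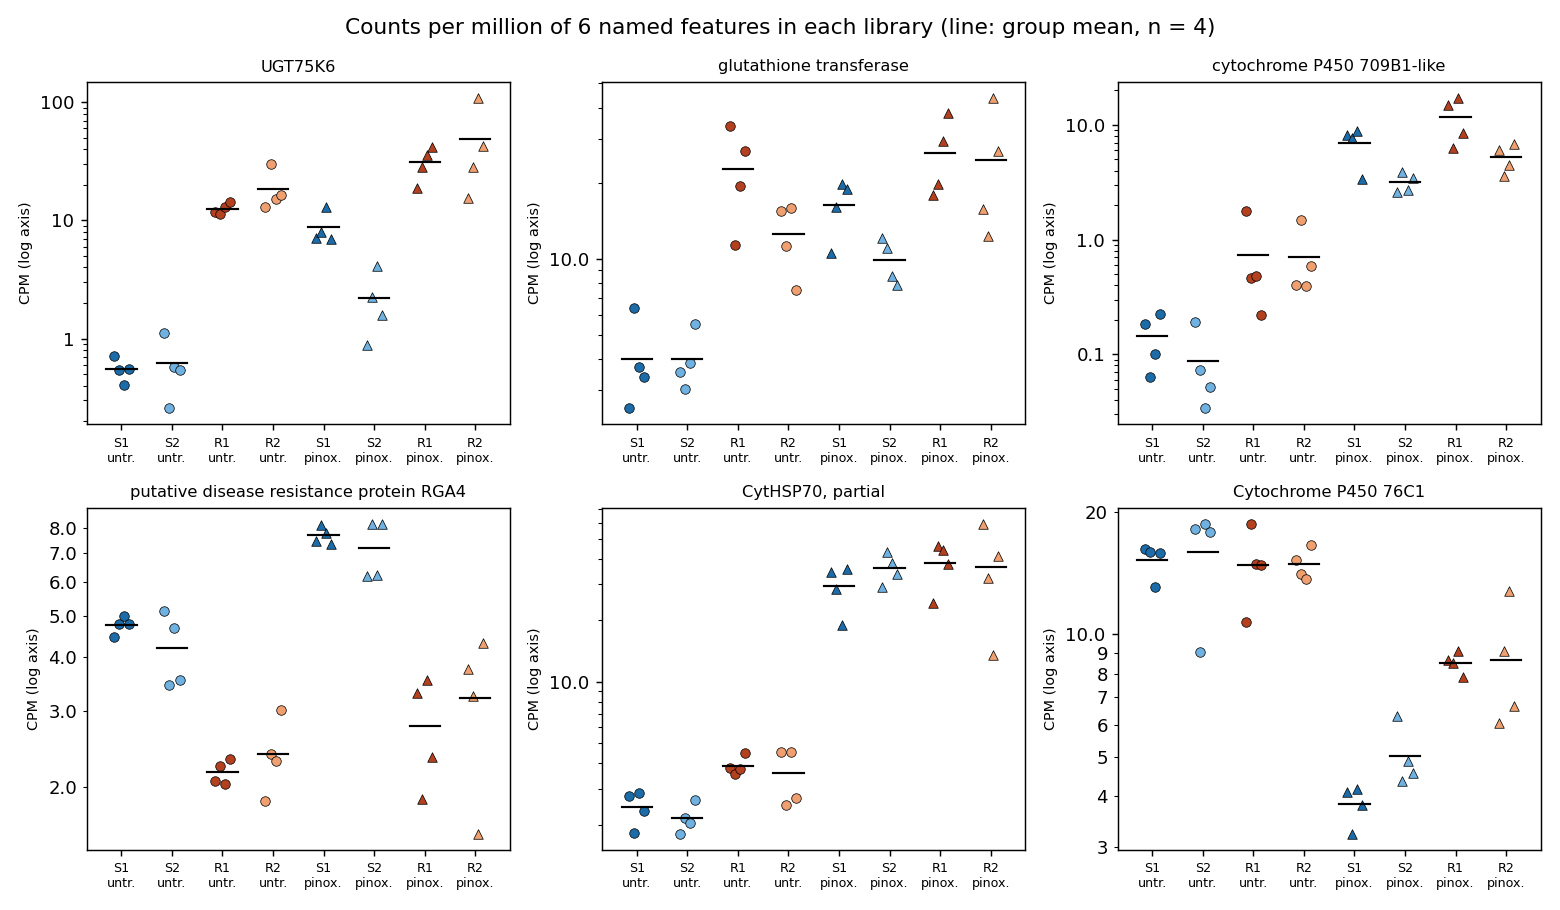
CPM on a log axis of 6 named features in each of the 32 libraries, by population and treatment, with a line at each group mean of 4 libraries. UGT75K6 had group means of 0.553 and 0.624 CPM in untreated S1 and S2 and of 12.6 and 18.6 in untreated R1 and R2; P450 76C1 fell from 15.2 to 3.83 CPM in S1.

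The response of susceptible plants to pinoxaden was read from sprayed against untreated libraries of S1 and S2. No mock spray and no harvest time are recorded for untreated plants. Effects of spraying itself or of harvest time therefore cannot be told apart from those of pinoxaden, here or in resistant plants. Chaperones and regulators of stress responses were among the rising transcripts. The dnaJ protein homolog (TRINITY_DN2682_c0_g1_i4.p1), a co-chaperone, rose by 3.07 ± 0.18, from 10.7 ± 1.99 to 83.5 ± 18.2 CPM in S1 and from 10.7 ± 1.12 to 96.4 ± 5.15 in S2 (SD, n = 4; adjusted p = 2.77e-12), and CytHSP70 (TRINITY_DN11298_c0_g1_i1.p2), a cytosolic heat shock protein, by 3.82 ± 0.23. NF-X1-type zinc finger protein NFXL1 (TRINITY_DN1664_c0_g1_i8.p1) rose by 3.96 ± 0.25 and ubiquitin-conjugating enzyme 28 (TRINITY_DN1202_c0_g3_i1.p1) by 1.42 ± 0.09. Eukaryotic translation initiation factor 6-2 (TRINITY_DN2098_c0_g1_i46.p2) went from 8 counts over the 8 untreated libraries to 5651 counts, a ratio of 676 with a 95% counting interval of 343 to 1570. Falling features included protein TSS (TRINITY_DN421_c0_g1_i16.p1) at -1.19 ± 0.09, Cytochrome P450 76C1 (TRINITY_DN3630_c0_g1_i3.p1) at -1.83 ± 0.15, a Polygalacturonase (TRINITY_DN7008_c0_g1_i11.p1), of the enzymes that cut pectin, at -1.54 ± 0.13, a MYB-related protein (TRINITY_DN492_c0_g1_i30.p2) at -1.11 ± 0.09 and tonoplast intrinsic protein 1-1 (TRINITY_DN1064_c1_g1_i1.p1), a water channel of the vacuole membrane, at -1.24 ± 0.11.

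Most detoxification and transport lists held more rising than falling members in susceptible plants. Most described features were called in this response: 7697 were tested, and only 250 of the 6347 called features carried no description. Of all calls more also rose (3384) than fell (2963). The counts below therefore do not set these lists apart from other described features. Of the glutathione S-transferases 10 of 16 rose and 1 fell (11 and 1 adjusted over the list alone); probable glutathione S-transferase parC (TRINITY_DN5305_c0_g1_i4.p1) rose by 5.60 ± 0.63, and glutathione S-transferase F11 (TRINITY_DN13935_c0_g1_i3.p1) fell by 0.32 ± 0.09. Of the glycosyltransferases 25 of 45 rose and 7 fell (27 and 8 adjusted over the list alone); UDP-glycosyltransferase 74F2-like (TRINITY_DN17_c0_g3_i1.p1) rose by 7.32 ± 0.50, and crocetin glucosyltransferase, chloroplastic-like (TRINITY_DN256_c0_g2_i1.p1) fell by 0.83 ± 0.16. Of the ABC transporters 25 of 43 rose and 12 fell (26 and 14 adjusted over the list alone); ABC transporter E family member 2 isoform X1 (TRINITY_DN5032_c0_g1_i13.p1) rose by 4.24 ± 0.39, and ABC transporter C family member 5 (TRINITY_DN12527_c0_g1_i6.p2) fell by 0.43 ± 0.08. With library totals alone the ABC count was 27 rising and 0 falling. Members of this list were taken by name, here and in resistant plants. Whether each one, ABC transporter E family member 2 included, carries compounds across membranes was not tested. The P450 list split evenly, with 15 of 44 rising and 14 falling (17 and 15 adjusted over the list alone; 10 and 10 of 35 without the cyclophilins and reductases; 18 and 5 with library totals alone); P450 709B1-like rose by 5.30 ± 0.43.

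Calls in the defence lists went in both directions in susceptible plants. WRKY factors rose in 17 of 19 cases and fell in 1 (18 and 1 adjusted over the list alone), with a WRKY protein (TRINITY_DN72249_c0_g1_i1.p1) at 2.70 ± 0.21 and probable WRKY transcription factor 53 (TRINITY_DN332_c0_g2_i3.p2) at -1.14 ± 0.39. Camera called the WRKY list with its preset correlation (adjusted p 0.000432) but not with the correlation estimated (0.357). In resistant plants these camera values were 0.000168 and 0.224. Pathogenesis-related members rose in 16 of 31 cases and fell in 8 (16 and 8 adjusted over the list alone), with pathogenesis-related genes transcriptional activator PTI6-like (TRINITY_DN108435_c0_g1_i14.p1) at 3.90 ± 0.28 and Glucan endo-1,3-beta-glucosidase 14 (TRINITY_DN10141_c0_g1_i14.p1) at -1.11 ± 0.11. That list caught 6 methionine enzymes by their names; without them 13 of 25 rose and 7 fell. NLR proteins rose in 11 of 36 cases and fell in 15 (11 and 16 adjusted over the list alone; 12 and 5 with library totals alone), with putative disease resistance protein At1g58400 isoform X1 (TRINITY_DN45997_c0_g1_i1.p1) at 2.87 ± 0.50 and putative disease resistance RPP13-like protein 3 (TRINITY_DN8122_c0_g1_i20.p1) at -1.29 ± 0.25. Receptor-like kinases rose in 30 of 86 cases and fell in 24 (33 and 32 adjusted over the list alone; 34 and 5 with library totals alone), with Receptor-like protein kinase HERK 1 (TRINITY_DN3957_c0_g1_i17.p1) at 0.93 ± 0.13 and proline-rich receptor-like protein kinase PERK4 (TRINITY_DN12873_c0_g1_i22.p1) at -1.11 ± 0.15. In all, 6347 features were called, 3384 rising and 2963 falling (7446 and 756 with library totals alone), and the count was 1654 without S1.

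**Figure D3:**
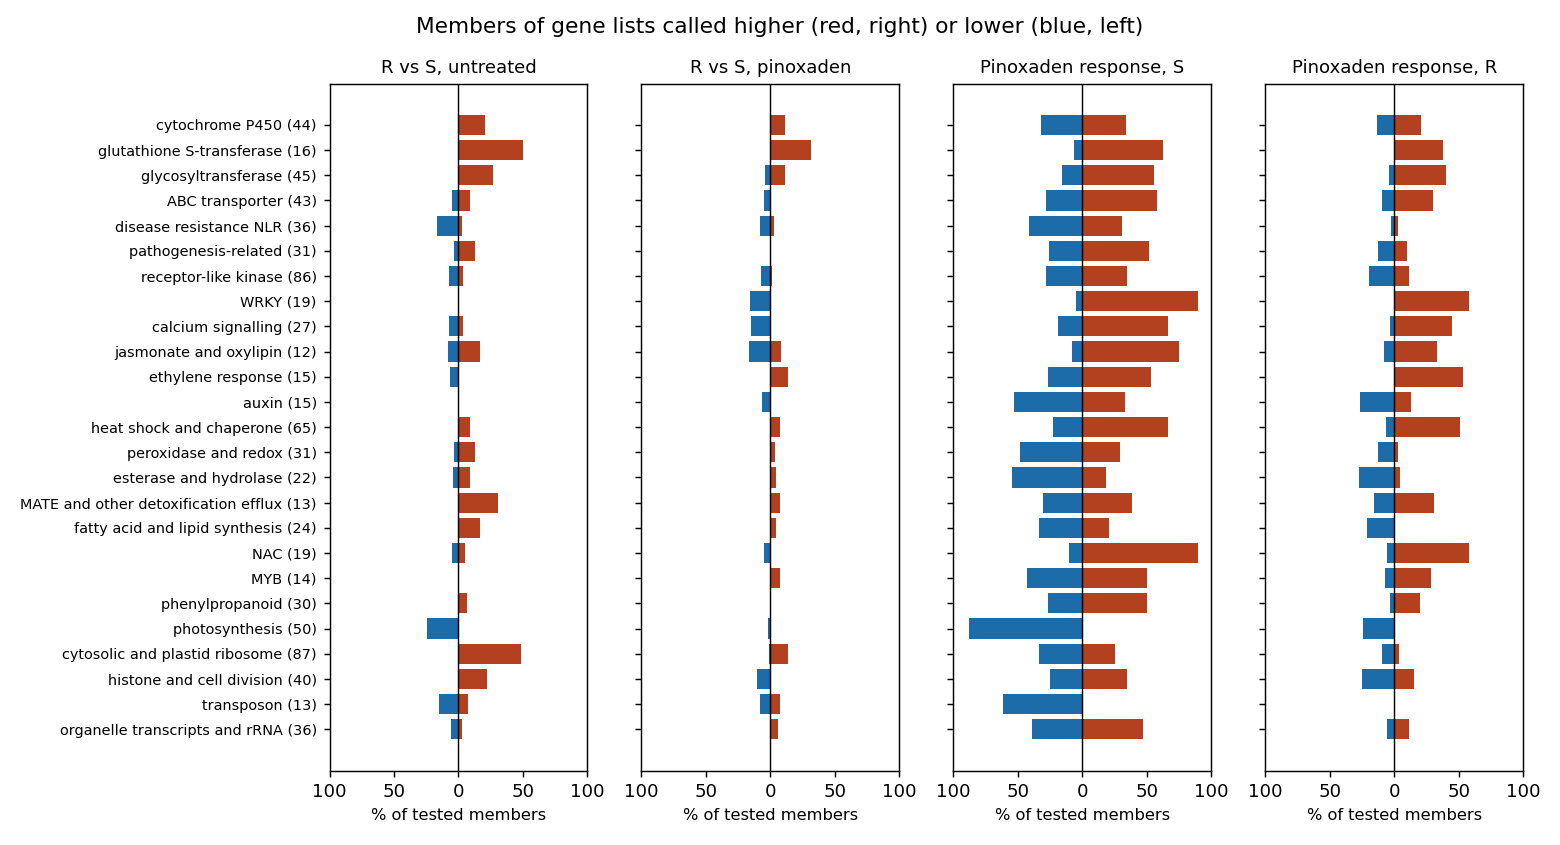
Percent of tested members of 25 gene lists called higher (right) or lower (left), with the number of members in brackets. Panels show the class comparisons in untreated and in sprayed plants and the responses of susceptible and of resistant plants. In the susceptible response 17 of 19 WRKY factors rose and 44 of 50 photosynthesis members fell; with library totals alone 18 rose and 21 fell.

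The response of resistant plants was read in the same way from R1 and R2, and the chaperones named above rose here too. The dnaJ protein homolog rose by 2.85 ± 0.17 and CytHSP70 by 3.32 ± 0.22, and NFXL1 rose by 3.35 ± 0.24 (adjusted p = 1.42e-11, 6.28e-11 and 2.35e-10). E3 ubiquitin-protein ligase RDUF1-like (TRINITY_DN9782_c0_g1_i2.p1) rose by 6.49 ± 0.44, from 0.0424 ± 0.0345 to 3.75 ± 1.18 CPM in R1 and from 0.0524 ± 0.0408 to 5.51 ± 3.3 in R2 (SD, n = 4). Eukaryotic translation initiation factor 6-2 went from 6 to 3071 counts, a ratio of 493 with a 95% counting interval of 226 to 1340. Of the falling features, putative alpha-L-fucosidase 1 (TRINITY_DN8468_c0_g2_i1.p1) fell by 1.03 ± 0.14, and expansin EXPA11 (TRINITY_DN2746_c0_g1_i8.p1) and Expansin-B11 (TRINITY_DN4162_c0_g1_i17.p3), which loosen walls of growing cells, by 1.21 ± 0.17 and 1.41 ± 0.21. Peroxidase 64 (TRINITY_DN17020_c0_g2_i1.p1) fell by 1.96 ± 0.31 and a GDSL-motif lipase/hydrolase-like protein (TRINITY_DN26058_c0_g1_i2.p1) by 2.03 ± 0.33.

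By list, 6 of 16 glutathione S-transferases, 18 of 45 glycosyltransferases and 13 of 43 ABC transporters rose in resistant plants, and 0, 2 and 4 fell (adjusted over the list alone, 11, 21 and 18 rose and 0, 6 and 6 fell). ParC rose by 3.93 ± 0.60, UDP-glycosyltransferase 74F2-like by 5.87 ± 0.47 and ABC transporter E family member 2 by 3.84 ± 0.40. Glycosyltransferase QUASIMODO1 (TRINITY_DN18989_c1_g1_i6.p1), which acts in pectin synthesis, fell by 0.80 ± 0.15, and ATP-binding cassette protein subfamily G member 5 (TRINITY_DN45757_c0_g2_i1.p1) by 0.71 ± 0.19 (adjusted p = 0.016). P450 members rose in 9 and fell in 6 of 44 cases (12 and 11 adjusted over the list alone), with P450 709B1-like at 3.42 ± 0.35 and a putative cytochrome P450 (TRINITY_DN70532_c0_g1_i3.p1) at -1.32 ± 0.22. WRKY factors rose in 11 of 19 cases and fell in 0 (12 and 0 adjusted over the list alone), with WRKY4 at 1.80 ± 0.16. NLR proteins were called in 2 of 36 cases, putative disease resistance protein At1g58400 (TRINITY_DN9296_c0_g1_i2.p1) at 0.98 ± 0.22 and putative disease resistance RPP13-like protein 3 (TRINITY_DN2399_c2_g1_i4.p1) at -1.12 ± 0.29; adjusted over the list alone the counts were again 1 and 1. Receptor-like kinases rose in 10 and fell in 17 of 86 cases (15 and 25 adjusted over the list alone), with HERK 1 at 0.78 ± 0.13 and probable inactive receptor kinase At2g26730 (TRINITY_DN44311_c0_g1_i1.p1) at -1.38 ± 0.24. Pathogenesis-related members rose in 3 and fell in 4 of 31 cases (8 and 7 adjusted over the list alone), with PTI6-like at 3.20 ± 0.28 and glucan endo-1,3-beta-glucosidase 7 (TRINITY_DN1254_c0_g1_i1.p1) at -0.75 ± 0.14. In all, 2288 features were called, 1409 rising and 879 falling, and the count was 380 without R1 and 1199 without R2.

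The features described as acetyl-CoA carboxylase were examined in both responses. Acetyl-coenzyme A carboxylase TRINITY_DN1720_c0_g2_i1.p1 fell by 0.28 ± 0.09 in susceptible plants (adjusted p = 0.0184) and by 0.34 ± 0.09 in resistant plants (adjusted p = 0.0143). Cytosolic acetyl-CoA carboxylase 2 TRINITY_DN1720_c0_g1_i7.p1 fell by 0.31 ± 0.09 in susceptible plants (adjusted p = 0.0121) and changed by -0.26 ± 0.09 in resistant plants (adjusted p = 0.0759). The fall in susceptible plants rests on the scaling: with library totals alone the values were 0.04 and 0.01, and without untreated S2 replicate 2 the first enzyme was no longer called. The call in resistant plants was also lost with library totals alone. The 2 responses did not differ detectably for either enzyme (-0.05 ± 0.13 with adjusted p = 0.914 and 0.05 ± 0.13 with adjusted p = 0.921).

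The responses of the classes, which share no libraries, overlapped. Features are not independent draws and both responses came from the same fit, so the Fisher p-values below do not measure the strength of evidence. Of the 1409 features rising in resistant plants 1246 (88.4%) also rose in susceptible plants, against 190.4 expected, and of the 879 falling ones 569 (64.7%) also fell, against 104 expected (one-sided Fisher's exact test over 25036 features, p below 1e-300 for each); 2 features were called in opposite directions. The overlap was 288 rising and 77 falling without R1 (38.72 and 10.55 expected), 778 and 213 without R2 (108.2 and 38.68 expected) and 729 and 233 without S1 (55.8 and 19.08 expected), and the falling overlap was 237 with library totals alone (16.52 expected). Across features, which are not independent replicates, the log2 fold changes had a Pearson correlation of 0.535, a Spearman correlation of 0.451 and a total-least-squares slope of 0.7395, resistant on susceptible. Among the 6818 features called in either class the correlation was 0.797, the slope 0.688, and 88.02% had the same sign. Susceptible plants alone had 6347 calls, so this selection favours larger susceptible folds.

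**Figure D4:**
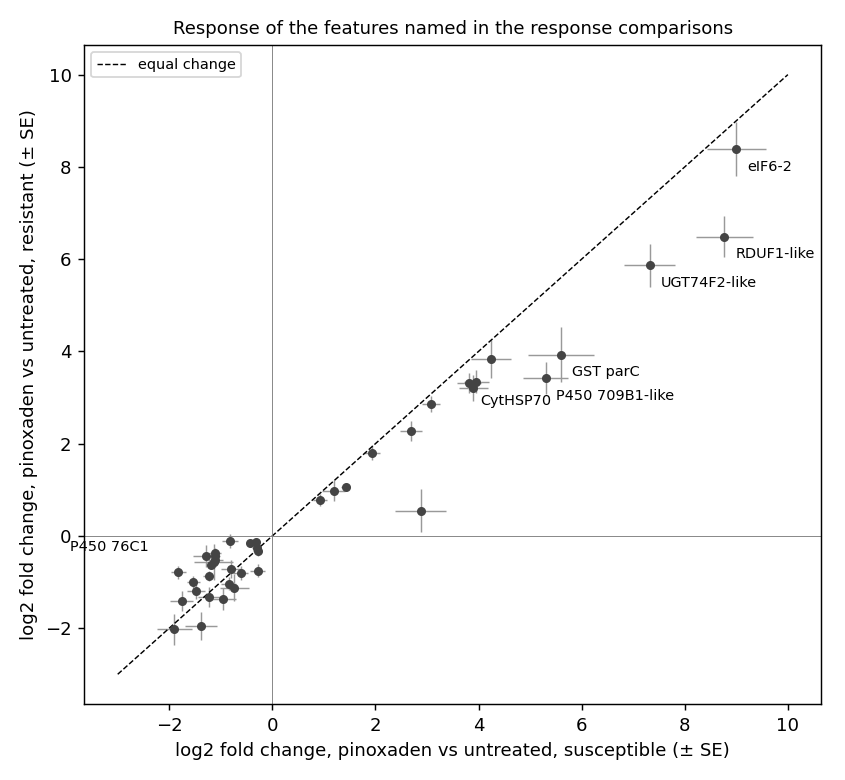
Log2 fold change after pinoxaden in susceptible (x axis) and resistant (y axis) plants, with SE, of the 41 features named in these responses; the dashed line marks equal change. All 16 features that are higher in both lie below the dashed line, but the difference between the responses was called for none of them (lowest adjusted p = 0.0945, quasi-likelihood F test). Of the 41 features 25 lie below the line: these 16 and some that fell more in resistant plants. The features were picked by smallest p in these responses, so their positions do not show a weaker resistant response. P450 76C1 lies at -1.83 on the x axis.

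Whether the responses differed was tested by the difference of the log2 fold changes, resistant minus susceptible. Cytochrome P450 76C1 fell less in resistant plants (difference 1.04 ± 0.20, adjusted p = 0.0212): from 15.2 ± 1.45 to 3.83 ± 0.434 CPM in S1 and 15.9 ± 4.58 to 5.03 ± 0.87 in S2, and from 14.8 ± 3.27 to 8.52 ± 0.508 in R1 and 14.9 ± 1.28 to 8.67 ± 3.07 in R2 (SD, n = 4). SRG1-like protein differed by 1.39 ± 0.30: it fell by 1.83 ± 0.30 in S1 and 1.03 ± 0.30 in S2, and was not called in R1 (0.56 ± 0.30) or R2 (-0.65 ± 0.295), whose estimates had opposite signs. F-box protein At5g04010 differed by 3.31 ± 0.72. UGT75E2 rose less in resistant plants, where it was already higher (difference -1.56 ± 0.35, adjusted p = 0.0387), and uclacyanin 1-like (TRINITY_DN27446_c0_g1_i1.p2) differed by -1.83 ± 0.40. NDR1/HIN1-like protein 6 (TRINITY_DN8863_c0_g1_i2.p1), named for regulators of defence, differed by -4.47 ± 0.76 at levels below 1 CPM in every group mean. Glucan endo-1,3-beta-glucosidase 14 differed by 0.74 ± 0.16, a glucan endo-1,3-beta-glucosidase (TRINITY_DN3963_c0_g2_i2.p1) by -0.78 ± 0.15 and cysteine-rich receptor-like protein kinase 20 by -1.78 ± 0.42.

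Low counts limit the fitted folds of several named features. Probable glutathione S-transferase GSTU6 isoform X1 (TRINITY_DN2663_c0_g3_i1.p1) had 0 counts in untreated susceptible plants. With a floor of 3 counts over the group it was 44.3-fold higher in untreated resistant plants and 59.3-fold higher in sprayed susceptible plants. The 95% counting intervals reached down to 35.5 and 47.8, so the floor values are no lower bounds. Endochitinase A-like (TRINITY_DN91150_c0_g1_i1.p1) had 1 count in untreated susceptible plants against 136 in untreated resistant (ratio 137, 95% counting interval 24.2 to 5450) and 34 in sprayed susceptible plants (ratio 32.5, interval 5.46 to 1320). F-box protein At5g04010 had 1 count in sprayed S1, so its fitted folds are not exact; summed over the classes it had 185 counts in sprayed resistant and 32 in sprayed susceptible plants (ratio 5.86, interval 4.01 to 8.81). RPP13-like TRINITY_DN35003_c0_g1_i1.p1 had 2 counts in sprayed S2 and 5 in untreated S2; its ratios from summed counts were 5.43 between the sprayed classes (interval 3.61 to 8.44) and 8 between the untreated classes (5.01 to 13.5). NDR1/HIN1-like protein 6 and parC had 4 and 8 counts in untreated S2, and RDUF1-like had 5 and 8 in untreated R1 and R2.

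The difference between the responses was called for 141 features, 97 positive and 44 negative (21 and 1008 with library totals alone), so this balance of directions depends on the scaling. By list, 1 P450, 1 pathogenesis-related and 0 other priority members had a positive difference. A negative one was called for 1 glutathione S-transferase, 2 glycosyltransferases, 3 pathogenesis-related members and 1 receptor-like kinase, and for no ABC transporter, NLR or WRKY member. Adjusted over the list alone, the positive and negative counts were 2 and 1 for P450, 0 and 5 for glutathione S-transferases, 1 and 8 for glycosyltransferases, 0 and 3 for ABC transporters, 1 and 4 for pathogenesis-related members, 8 and 6 for receptor-like kinases and 0 for NLR and WRKY members. The count of 141 moved by over 1.5 times without each of 21 libraries. Among untreated libraries these were S1 replicates 1, 3 and 4 (44, 87 and 46), S2 replicates 1, 2, 3 and 4 (90, 381, 38 and 74), R1 replicates 1 and 2 (37 and 262) and R2 replicates 1, 2 and 3 (55, 40 and 41). Among sprayed libraries these were S1 replicates 1 and 2 (63 and 26), S2 replicates 2 and 3 (28 and 48), R1 replicates 2, 3 and 4 (69, 28 and 214) and R2 replicates 2 and 3 (41 and 39). With edgeR it was 0 without S1 and 0 without R1, 2 without R2 and 567 without S2. Of the named features, P450 76C1 and NDR1/HIN1-like protein 6 were called after leaving out any single library, though neither was called without R1, without R2, without S1 or with the replicate block within population. The call was lost without 1 library for glucan endo-1,3-beta-glucosidase TRINITY_DN3963_c0_g2_i2.p1, 5 for endochitinase A-like, 11 for Glucan endo-1,3-beta-glucosidase 14, 12 for SRG1-like protein, 12 for F-box protein At5g04010, 16 for uclacyanin 1-like, 17 for UGT75E2, 21 for GSTU6 isoform X1 and 25 for receptor-like protein kinase 20, each of 32 left out in turn. Features at an unadjusted p under 0.05 numbered 3598 over all libraries.

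Each population was also compared with its own untreated plants. The response was called for 5000 features in S1 (2736 rising, 2264 falling), 1804 in S2 (1152 and 652), 1425 in R1 (961 and 464) and 411 in R2 (321 and 90), with 6904 and 466 in S1, 1901 and 203 in S2 and 345 and 44 in R2 with library totals alone. Fewer calls do not show a smaller response: the R2 response differed from that of R1 for 1 feature (1435 at an unadjusted p under 0.05) and the S2 response from that of S1 for 7 (2052 at an unadjusted p under 0.05). The R1 count was 919 and 896 without untreated R1 replicates 3 and 4 and 923 without sprayed R1 replicate 3. The R2 count was 254 without untreated R2 replicate 1 and 222 without sprayed R2 replicate 1.

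**Figure D5:**
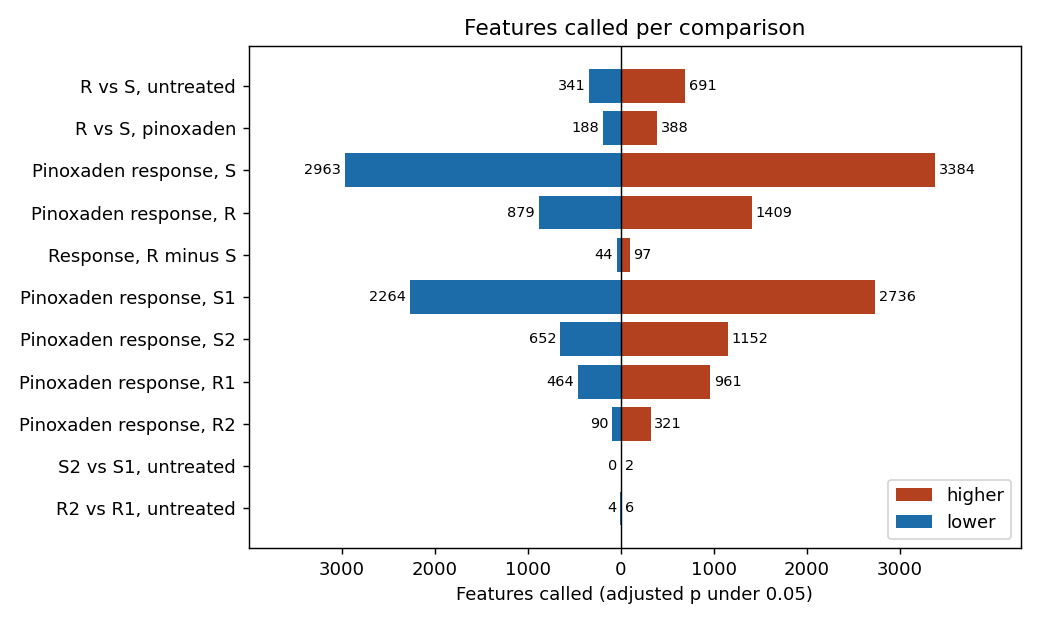
Features called per comparison, rising or higher to the right and falling or lower to the left, at an adjusted p under 0.05. The susceptible response had 3384 and 2963 calls, the resistant response 1409 and 879.

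Populations of 1 class served as the background of the class difference. Untreated S2 and S1 differed for 2 features and untreated R2 and R1 for 10 (4 against 4 libraries; 1364 and 1997 features at an unadjusted p under 0.05). Between the classes, single pairs of untreated populations, also 4 against 4 libraries, gave 153 higher and 60 lower features in R1 against S1, 225 and 124 in R1 against S2, 56 and 13 in R2 against S1, and 58 and 31 in R2 against S2. Between the untreated classes, 22 features were called with the same sign in each of the 4 pairs of a resistant and a susceptible population, 20 higher and 2 lower in resistant plants. Both other ways of pairing the populations gave 0 such features with edgeR, and 4 and 3 features when the pairs were averaged; 3 pairings are too few for a p under 0.05. Most of the 22 features, among them the 2 lower ones, were described only as unnamed, uncharacterized or hypothetical, and some shared a contig. The others included UGT75K6, UGT75E2 and the alanine--glyoxylate aminotransferase. Chosen after their values were seen, UGT98B4 (TRINITY_DN2286_c1_g1_i7.p1) at 1.60 ± 0.25, putative glutathione S-transferase GSTU6 (TRINITY_DN2663_c0_g2_i2.p1) at 4.11 ± 0.55, sulfite exporter TauE/SafE family protein 4 (TRINITY_DN3389_c0_g1_i17.p1) at 0.99 ± 0.12 and DNA polymerase delta subunit 4 (TRINITY_DN14325_c0_g1_i1.p1) at 1.13 ± 0.17 were also among them.

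The authors' deposited table lists 1412 features for the untreated class comparison, 656 for the sprayed class comparison, 6577 for the susceptible and 2430 for the resistant response. Of these 938, 459, 6065 and 2107 were called here, each with the same sign as listed.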

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

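The test of how much of each fold remained without 1 library, the comparison of the 3 pairings of populations, the SD of the response score, and the count of real labels in the highest split were chosen after the results were seen.

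The untreated class difference of 1032 features depended on untreated R1 replicate 1, and 298 were called without it, 289 of them among the 1032; without other untreated libraries the count was 465, 605 and 609 (S1 replicates 1, 2 and 4), 459 and 631 (S2 replicates 3 and 4) and 473 and 386 (R2 replicates 2 and 3). The folds themselves kept a median of 91.3% (interquartile range 18.9, 5th percentile 64.1), which argues against this library as the only source of the folds. All 1032 also kept their sign. Signs carry little weight here, since the features were called with this library included and all other libraries were the same. The median ratio of fold to SE fell from 3.86 to 3.47 (median SE 0.197 to 0.179), yet 597 features, 558 of them among the 1032, lay at or below the earlier last called p of 0.00206; with 3853 features at unadjusted p under 0.05 instead of 4847 the adjustment was also stricter. A condition of the untreated arm alone may contribute: 70.4% of the called features had the same sign after spraying, against 54.6% of all features, and the design does not separate this from a class difference. More dividing tissue in resistant samples cannot be told apart either. A covariate for the share of the histone and cell-division list kept a median of 70.9% of the folds (interquartile range 55.8). With it 148 features were called, 131 of them shared, with a median SE of 0.207. That list also takes in kinesins, tubulins and expansins. Its members carry descriptions only because the study had listed them on these same libraries. A heritable difference of the resistant populations stays open and was not tested.

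Untreated resistant plants lay along the response of susceptible plants: 297 features were higher in both against 93.4 expected, 160 lower in both against 40.4, and 11 and 8 were opposite against 81.8 and 46.1. Both comparisons use the untreated susceptible libraries, which alone gave a covariance of 0.0597 ± 0.00201 in 20 simulations without change (SD), against 0.122 observed, while the correlation went the other way, 0.501 in the simulations against 0.327 observed. With these libraries split between the comparisons the covariance was 0.0599 ± 0.00869 over 36 splits (SD, lowest 0.0431), which argues against shared libraries as the whole source. The mean correlation over these splits was 0.138, a weak relation across features. The SD is over splits of the same libraries and does not measure variation between libraries. The covariance was 0.0427 ± 0.00836 without untreated R1 replicate 1, and 0.071 in R1 (0.0366 ± 0.00913 without its untreated replicate 1, lowest 0.0195) and 0.0489 in R2 alone, which argues against 1 library and against 1 population. A baseline shift in both resistant populations may explain it, as a hypothesis found on these data, and a difference in growing or harvest conditions between the classes stays open.

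R2 had 411 called features after spraying against 1425 in R1, with a lower slope on the susceptible response (0.513 against 0.658). The count was 254 without untreated R2 replicate 1 and 222 without sprayed R2 replicate 1, and the R1 count was 919 and 896 without untreated R1 replicates 3 and 4 and 923 without sprayed R1 replicate 3. The spread within R2 groups was 0.913 of that of the other populations and its mean depth outside the 10 most abundant features was 12317407 counts, against 10541786 in R1, which argues against depth and against wider spread over all features; the SD of the response score of its sprayed libraries was 0.431, against 0.0889 in R1, 0.257 in S1 and 0.284 in S2, and with 4 libraries each spread of the response itself stays open. The lowest response score of a sprayed R2 library was 0.859, above the highest untreated score of 0.187, which argues against unsprayed libraries. A weaker or later response in R2 may explain the counts, but the direct test against R1 called 1 feature.

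Other splits of the same libraries were refitted with simpler models that used only the libraries compared. For the class comparisons and the difference between responses, these models left the populations out. Real counts in this paragraph therefore differ from the main counts. Only 1 split, the real one, reached the real count in each of 11 comparisons. Between untreated S2 and S1 the margin was 1 feature and the test over all libraries called 2, so chance is not taken as excluded there. Nor is it for untreated R2 and R1 (8 against 3) or the difference between responses (13 against 5), where counts were small. In the other comparisons the real grouping called more features than every other split drawn, with no correction over the 11 comparisons. For the class comparisons and the difference between responses the splits exchange single libraries. They therefore speak to the grouping of libraries and not to which 2 populations form a class. The real count and the highest of the other splits were 450 and 1 for the untreated classes, 106 and 7 for the sprayed classes, 5723 and 3190 for the susceptible and 1999 and 100 for the resistant response (100 splits each), and 13 and 5 for the difference between responses (60 splits). They were 4003 and 4 in S1, 1030 and 4 in S2, 791 and 2 in R1, 108 and 3 in R2, 5 and 4 between untreated S2 and S1, and 8 and 3 between untreated R2 and R1 (35 splits each). The split of the susceptible response that called 3190 kept the real label in 14 of 16 libraries, more than any other split. For the 22 features shared by all 4 population pairs, 3 pairings are too few for a share under 0.05; the real pairing gave 22, the others at most 0.

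The responses of the classes differed for 141 features, a difference tested by the interaction term. Named ones were Cytochrome P450 76C1 (1.04 ± 0.20), SRG1-like protein (1.39 ± 0.30), F-box protein At5g04010 (3.31 ± 0.72), Glucan endo-1,3-beta-glucosidase 14 (0.74 ± 0.16), NDR1/HIN1-like protein 6 (-4.47 ± 0.76), endochitinase A-like (-7.87 ± 1.59), uclacyanin 1-like (-1.83 ± 0.40), GSTU6 isoform X1 (-4.33 ± 0.96), UGT75E2 (-1.56 ± 0.35), the glucan endo-1,3-beta-glucosidase TRINITY_DN3963_c0_g2_i2.p1 (-0.78 ± 0.15) and cysteine-rich receptor-like protein kinase 20 (-1.78 ± 0.42). The folds of GSTU6 isoform X1 and endochitinase A-like rest on groups with 0 and 1 counts and that of F-box protein At5g04010 on 1 count in sprayed S1, and they are no bounds. Only P450 76C1 and NDR1/HIN1-like protein 6 were called after leaving out any single library.

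A single library stood far from the other 3 of its group in 44 of 688 groups tested; chance marks about 1 in 20, or 34.4. Where the other 3 libraries held no count, the test marks the remaining library by construction, from a few counts. Of the composition measures, the 10 most abundant features held 64.7% in untreated R2 replicate 4 (others 65.8 to 66), and transport transcripts of other organs 0.0196% in sprayed R2 replicate 1 (others 0.017 to 0.0173). The remaining values are CPM of named features, with the range of the other 3 libraries in brackets. In untreated S1: P450 TRINITY_DN884_c0_g1_i6.p1 15.9 in replicate 1 (12.5 to 12.7), eukaryotic translation initiation factor 6-2 0.064 in replicate 2 (0), ABC transporter C family member 5 10.6 in replicate 2 (13.3 to 13.6), P450 76C1 13.1 in replicate 3 (15.8 to 16.2) and inactive receptor kinase At2g26730 4.23 in replicate 3 (2.05 to 2.24). In untreated S2: endochitinase A-like 0.0273 in replicate 1 (0), and in replicate 2 UGT75E2 0.366 (0.957 to 1.09), acetyl-coenzyme A carboxylase 355 (227 to 242), P450 76C1 9.07 (17.8 to 18.7) and crocetin glucosyltransferase 6.29 (11.8 to 13.4); in replicate 4 ABC transporter B family member 20-like 0.939 (0.629 to 0.658) and Polygalacturonase 16.9 (12.3 to 12.7). In untreated R1: initiation factor 6-2 0.116 in replicate 1 (0), putative polyprotein 0.0385 in replicate 2 (0), alpha-L-fucosidase 1 5.07 in replicate 3 (7.16 to 7.55) and MYB-related protein 27.3 in replicate 4 (24.8 to 25.1). In untreated R2: the WRKY protein 3.63 in replicate 2 (4.6 to 4.62), initiation factor 6-2 0.0464 in replicate 3 (0), and in replicate 4 F-box protein At5g04010 1.04 (1.97 to 2.18), Polygalacturonase 11.2 (13.3 to 13.6) and glucan endo-1,3-beta-glucosidase TRINITY_DN3963_c0_g2_i2.p1 5.85 (4.73 to 4.78).

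In sprayed S1, F-box protein At5g04010 had 0.0257 CPM in replicate 1 (others 0), Glucan endo-1,3-beta-glucosidase 14 6.3 in replicate 2 (7.8 to 8.14), and in replicate 4 P450 709B1-like 3.37 (7.63 to 8.87), ABC transporter B family member 20-like 0.986 (1.46 to 1.52) and the dnaJ protein homolog 111 (72.3 to 75.7). In sprayed S2, tonoplast intrinsic protein 1-1 had 162 in replicate 1 (144 to 147), RPP13-like TRINITY_DN35003_c0_g1_i1.p1 0.0567 (0) and glutathione S-transferase F11 15 (17.9 to 18.5) in replicate 2, ABC transporter G family member 38-like 0.74 (0.408 to 0.44) and ABC transporter C family member 5 8.86 (9.91 to 10.1) in replicate 3, and in replicate 4 F-box protein At5g04010 0.643 (0.113 to 0.136), RPP13-like protein 3 TRINITY_DN8122_c0_g1_i20.p1 2 (3.67 to 3.8) and NDR1/HIN1-like protein 6 2.03 (0.355 to 0.482). In sprayed R1, Reticulon-like protein B8 had 2.37 (4.14 to 4.58) and the dnaJ protein homolog 55.3 (80.8 to 86.4) in replicate 1, cysteine-rich receptor-like protein kinase 10 0.814 in replicate 2 (1.09 to 1.13), and in replicate 4 kinase 6 7.51 (5.47 to 5.6) and endochitinase A-like 0.105 (0). In sprayed R2, Reticulon-like protein B8 had 2.5 (1.85 to 1.89) and WRKY4 12.6 (6.49 to 7.13) in replicate 1, and putative polyprotein 0.0236 in replicate 4 (0).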

How the results depend on the processing

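The histone covariate, the sums per contig and the removal of the 10 most abundant features were chosen after the data were seen. The cause of each change below was not tested, except that stricter thresholds call fewer features by construction. The competitive list test against all features was not run, since only listed features carry a description. Over 104 named-feature results, median-of-ratios factors and removal of the 10 most abundant features left all 104 on the same side of the threshold; leaving out single libraries left 3144 of 3328, with 181 lost, 3 gained and 0 reversed. Calls were lost in 31 of the 104 without R1, 28 without S1, 23 without R2 and 16 without S2, in 11 with limma-voom, 11 with 4 groups and 9 with library totals alone. They were lost in 10 of 38 with population as a random block, 10 of 66 with the replicate block within population and 4 of 21 with the histone covariate. Sums per contig and removal of the 10 most abundant features kept every count within 1.5 times.

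An absolute log2 fold change of at least 1 gave 404 features for the untreated and 163 for the sprayed classes, 1991 and 833 for the susceptible and resistant responses, 40 for their difference, 2215 in S1, 938 in S2 and 852 in R1, with an overlap of 559 rising and 90 falling. An adjusted p under 0.01 gave 167, 155, 4198, 1167 and 4 in the same order, 3041 in S1, 862 in S2, 621 in R1 and 207 in R2, 0 between S2 and S1, 3 between R2 and R1, 6 in all 4 pairs, and an overlap of 766 and 228.

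Library totals alone gave 3265 and 311 for the untreated and sprayed classes, 1029 for the difference between responses, 5 between R2 and R1, 36 in all 4 pairs and a falling overlap of 237. Acetyl-coenzyme A carboxylase TRINITY_DN1720_c0_g2_i1.p1 and cytosolic acetyl-CoA carboxylase 2 TRINITY_DN1720_c0_g1_i7.p1 reversed sign in the susceptible response, to 0.03749 and 0.009045. No low-count filter gave 4 between S2 and S1, 3 between R2 and R1 and a correlation of 0.343. A filter of at least 1 CPM in at least 4 libraries gave 266 for the difference between responses and a correlation of 0.637.

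DESeq2 gave 1841 and 1109 for the untreated and sprayed classes, 656 for the difference between responses, 715 in R2, 57 between S2 and S1, 123 between R2 and R1 and a correlation of 0.425. Limma-voom gave 635 for the untreated classes, 85 for the difference, 268 in R2, and 4 and 1 between S2 and S1 and between R2 and R1. With the replicate number as a block over all groups, R2 and R1 differed for 3 features; with the replicate block within population the difference between responses was 17 and R2 246. With 4 groups of class by treatment the sprayed classes gave 316 and the difference 13. Population as a random block gave 166 and 253 for the untreated and sprayed classes (consensus correlation 0.0289). Fitting only the libraries compared gave 402 for the untreated classes, 1030 in S2, 791 in R1, 108 in R2 and 5 between S2 and S1. The histone covariate gave 148 for the untreated classes.

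Without R1, the untreated classes gave 200, the resistant response 380, the difference between responses 0 and the overlap 288 and 77, with a correlation of 0.431. Without R2, the sprayed classes gave 120, the resistant response 1199, the difference 2 and the overlap 778 and 213, with a correlation of 0.428. Without S1, the untreated and sprayed classes gave 187 and 98, the susceptible response 1654, the difference 0 and the overlap 729 and 233. Without S2, the untreated and sprayed classes gave 144 and 1204 and the difference 567, with a correlation of 0.456.

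Leaving out each library in turn gave 298 to 1456 for the untreated classes, 304 to 758 for the sprayed classes, 5794 to 6543 and 1747 to 2543 for the susceptible and resistant responses, 26 to 381 for their difference, 4109 to 5210 in S1, 1230 to 2057 in S2, 896 to 1544 in R1 and 222 to 475 in R2. It gave 1 to 3 between S2 and S1, 3 to 17 between R2 and R1, an overlap of 1017 to 1503 and 413 to 652, and a correlation of 0.495 to 0.569. Changes beyond 1.5 times follow, by library left out, where U stands for untreated classes, T for sprayed classes, D for the difference between responses, P for a response in 1 population and B for untreated R2 against R1. Untreated S1: replicate 1 U 465, D 44; 2 U 605, B 5; 3 D 87; 4 U 609, D 46, B 6. Untreated S2: 1 D 90; 2 D 381, B 17; 3 U 459, D 38, B 6; 4 U 631, D 74. Untreated R1: 1 U 298, D 37, B 4; 2 D 262, B 3; 3 P 919; 4 P 896, B 5. Untreated R2: 1 D 55, P 254, B 6; 2 U 473, D 40, B 4; 3 U 386, D 41, B 3; 4 B 6. Sprayed S1: 1 D 63, B 5; 2 D 26, B 6; 3 B 5; 4 B 6. Sprayed S2: 2 T 349, D 28, B 5 and 1 feature between S2 and S1; 3 D 48, B 4; 4 B 6. Sprayed R1: 2 D 69, B 4; 3 D 28, P 923; 4 D 214. Sprayed R2: 1 P 222; 2 T 371, D 41, B 6; 3 T 304, D 39.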

Other observations

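The list tests among described features and the examples in this part were chosen after the values were seen.

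Ribosomal, growth-related and photosynthesis lists held called members in the untreated class comparison. With the correlation estimated per list, camera called none of them (adjusted p 0.254 for ribosome, 0.447 for histone and cell division, 0.227 for photosynthesis). Of 87 ribosomal features 42 were higher in untreated resistant plants and 0 lower (49 and 0 adjusted over the list alone; 61 and 0 with library totals alone, 6 and 0 without untreated R1 replicate 1), with 60S ribosomal protein L15-2 (TRINITY_DN146_c0_g3_i1.p1) at 0.80 ± 0.15; the 22 plastid ribosomal features held none of these calls. Of 40 histone and cell-division features 9 were higher (15 and 1 lower adjusted over the list alone; 1 without untreated R1 replicate 1), with kinesin-like protein KIN-4C (TRINITY_DN22686_c0_g1_i3.p1) at 2.89 ± 0.55. Of 50 photosynthesis features 12 were lower (15 adjusted over the list alone; 4 with library totals alone and 5 without untreated R1 replicate 1), with photosystem II CP47 (TRINITY_DN277_c1_g1_i1.p1) at -0.33 ± 0.07. Detoxification efflux carriers were higher in 4 of 13 cases and fatty acid and lipid synthesis in 4 of 24 (5 and 10 adjusted over the list alone, with 1 lower in each), with 3-ketoacyl-CoA synthase 12-like (TRINITY_DN143_c0_g3_i1.p1) at 2.19 ± 0.41. From the jasmonate and oxylipin list, 12-oxophytodienoate reductase 1 (TRINITY_DN38527_c0_g1_i1.p1) was 3.88 ± 0.66 higher, while lipoxygenase TRINITY_DN561_c0_g1_i1.p1 was lower, at -1.35 ± 0.28. Camera with the estimated correlation did not call that list (adjusted p 0.869). These lists hold features that the study chose on these samples.

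After spraying, more heat shock and NAC members rose than fell in both classes, and of the MYB factors 7 rose and 6 fell in susceptible and 4 and 1 in resistant plants (7 and 7, and 5 and 2, adjusted over the list alone). With the correlation estimated per list, camera called neither the heat shock nor the NAC list (adjusted p 0.357 in susceptible and 0.224 in resistant plants for each). Of 65 heat shock and chaperone features 43 rose and 15 fell in susceptible and 33 and 4 in resistant plants (45 and 17, and 41 and 11, adjusted over the list alone). Of 19 NAC factors 17 rose and 2 fell in susceptible plants and 11 and 1 in resistant plants (17 and 2, and 11 and 2, adjusted over the list alone), with NAC domain-containing protein 68-like (TRINITY_DN767_c1_g1_i1.p3) at 3.62 ± 0.34. Photosynthesis features fell in 44 of 50 cases in susceptible and 12 in resistant plants, with Rubisco activase beta form (TRINITY_DN843_c0_g1_i20.p1) at -0.61 ± 0.08; 21 and 9 fell with library totals alone. Camera with the estimated correlation did not call the photosynthesis list either (adjusted p 0.357 in susceptible and 0.335 in resistant plants). Ribosomal features rose in 22 and fell in 29 of 87 cases in susceptible plants, a direction that turned to 47 and 7 with library totals alone, as did peroxidase and redox features (9 and 15, to 11 and 4), esterases (4 and 12, to 6 and 4) and fatty acid synthesis (5 and 8, to 6 and 1). Taken apart, the 22 plastid ribosomal features rose in 4 and fell in 18 cases, and the other 65 ribosomal features rose in 18 and fell in 11. Probable carboxylesterase 15 (TRINITY_DN862_c1_g1_i1.p1) rose by 4.66 ± 0.55 and 3.25 ± 0.53 in the 2 classes. In sprayed plants, 12 of the 22 plastid ribosomal features were higher in resistant plants (0 of 87 ribosomal features with library totals alone).

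Among the 7697 described features, themselves chosen by the study, camera with its preset correlation called 8, 6, 4, 11 and 3 of 28 lists for the untreated classes, sprayed classes, susceptible response, resistant response and their difference. With the correlation estimated per list it called 0 in each (lowest adjusted p 0.223, 0.276, 0.357, 0.224 and 0.326), while the rotation test fry called 11, 13, 18, 18 and 4 with direction and 22, 25, 28, 24 and 18 without, so no call of the preset holds when the correlation is estimated.

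As a check of pairing, 2 libraries correlated best with the library of the other treatment that bears their own number, and the correlations of such libraries lay between -0.0845 and 0.0884. Checks for duplicates gave a chi-square per degree of freedom between 12.98 and 113.7 for every pair of libraries of a group, where copies of 1 library would give about 1.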
